A study of Mus musculus with 10 samples.

How the data were processed

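Islets were taken from 5 db/db and 5 db/+ mice at 9 weeks, and each mouse's RNA was hybridised to 1 array of 2 colours. Per the labels, total RNA was extracted with Trizol and amplified in 2 rounds from 100 ng, the islet RNA of each replicate was labelled with Cy5 and a control reference with Cy3, given as islet RNA of db/+ mice of 9 weeks. All 10 arrays had the same dye orientation, so a dye effect of a gene that is alike on every array cancels in the difference of the groups. A dye effect that varies with the signal would not cancel, and the Cy3 signal of some genes differed between the groups. The labels call the samples biological replicates.

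Scanned images were read with Agilent Feature Extraction 8.5.1.1, per the submitters' processing notes. Deposited intensities were given, per the file headers, for both channels of each array, in arbitrary units mostly rounded to 0.01. The authors' p-value for each probe and array compares both channels, by a method not given in the sources used here. The deposited series values are log10 ratios, and were checked to equal the log10 of the Cy5 intensity of the islet sample over the Cy3 intensity of the reference. The median log10 ratio was 0 on every array, and no centring of genes was seen. Background subtraction, dye normalization and the step that left spots blank are not given in the sources used here. Of 23512 probes, 21954 had a value on all arrays and 1558 were blank on some. Blanks took 49.1% of the values of the 262 probes of intensity 15 or more and 3.51% of those under 0.05 units, so genes of the highest abundance are under-represented. Rounding makes ratios of dim probes coarse, and 27.5% of the Cy3 values were at or under 0.05 units.

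The array's gene symbols were matched to the RefSeq table of assembly GRCm38.p6, by current symbol for 18956 probes, by accession for 613 and by synonym for 1775. For 913 probes the file's own symbol was kept and 1255 had none. The files name no genome build, and no coordinates are given. The 10 deposited log10 columns were turned into log2 ratios with no pseudocount and no further scaling. Probes with at least 3 values in each group were kept (23138), and each gene was represented by its probe of highest mean Cy3 intensity, giving 19557 genes. Of 2026 genes with several tested probes, 44 had probes called in opposite directions. Among genes named below, Pdia3, H2-DMa, Rrm2, Uqcrh, Nr1d1, Per3 and Rdh10 had 2 tested probes of which only 1 was called. A gene was called dim when its mean intensity in the reference and in both groups was under 0.049 units, the lower quartile of the probes.

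Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no covariate, Benjamini-Hochberg adjustment over all genes, threshold 0.05). All adjusted p-values for genes are limma's and are 2-sided. Folds are 2 to the power of the log2 difference of the group means, and SE is the moderated standard error. Lists of at least 5 genes were tested with camera on the genes with 10 values (correlation preset at 0.01, with an estimated correlation beside it) and with fry, adjusted over the 35 lists. The Cy3 channel was tested in the same way after quantile normalization, as a negative control. Scores per array are medians of the log2 ratios over the genes of a list, compared by 2-sided exact permutation tests, whose smallest p is 0.00794 with 5 against 5. Groups, tests, lists, the rule for named genes and most alternatives were set before the data were examined. Named genes are the 10 largest rises and falls among called genes separated on all 10 arrays that have a proper symbol, 12 fixed genes, and up to 4 genes of smallest adjusted p per list, and not all of them are given. Genes with blank values are given as ratios to the reference.

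The fit was tested on simulated data with the spread and blanks of the 19557 genes, in which 200 genes were changed. It recovered 59% of those changed 1.5-fold and 89% of those changed 2-fold, with 4.52% false genes among the calls. Far fewer genes were changed than the 35.2% called in the data, and the rounding of dim values was not simulated. These rates therefore do not carry over to the real comparison. The list test called the shifted list of 40 genes and 0 of 34 unshifted lists. Simulated genes were independent of each other, so that result does not cover correlated genes. Alternatives covered the normalization between arrays, the Cy5 signal without the reference, filters on dim probes, the handling of several probes, trended and weighted fits, the replicate number as a block, an acinar covariate, other thresholds, an exact permutation test per gene and leaving out each array. Loess within arrays, a list test on all genes and leaving out both arrays of largest spread were added after the data were seen. The remaining steps and the figures used Python 3.11.15, pandas 2.3.3, matplotlib 3.10.9 and version 1.17.8 of data.table. Ranges of adjusted p over all alternatives leave out fry and the estimated correlation, which are given for themselves.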

Results

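Gene expression was measured in pancreatic islets of 9-week-old mice that carry 2 copies of the db allele of the leptin receptor gene (db/db) and of lean db/+ controls on the C57BLKS/J background. The db/db mouse is obese and insulin resistant, and the labels place 9 weeks at a stage of severe hyperglycaemia with raised insulin that has declined from an earlier age. There were 5 biological replicates per group, each on 1 array of 2 colours, with the islet RNA of the replicate in Cy5 and a control reference in Cy3, labelled as islet RNA of db/+ mice of 9 weeks. Each array held values for 22657 to 23365 of 23512 probes, and the number of arrays limits the precision. The comparison asks which genes are higher or lower in db/db islets than in db/+ islets.

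Islets of db/db mice differed widely from those of db/+ mice. Among named genes separated on all arrays, Cyp26b1 and Aldh1a3 rose most in the ratio to the reference. They encode enzymes that break down and make retinoic acid. The largest falls among such genes were in the immediate early gene Fosb and in Cox6a2, a subunit of cytochrome c oxidase. Beta cell genes such as Kcnj11 and Gipr and the genes of cholesterol synthesis were lower in db/db. Among tested genes of the extracellular matrix, the endoplasmic reticulum, the interferon response and the Reg family, more rose than fell. As lists these passed with a preset correlation between genes and did not pass with an estimated one (adjusted p = 0.207 to 0.469). Of 19557 genes tested with limma, 3348 were higher and 3545 lower in db/db at an adjusted p under 0.05, together 35.2% of the genes tested. A change of at least 2-fold was seen in 607 of the higher and 301 of the lower genes. All 5 db/db arrays lay above all 5 db/+ arrays for 2406 genes and below them for 2455, among 18627 genes with 10 values, where chance gives a share of 0.00794 for both directions together. The median log2 difference over all genes was -0.02. Quantile normalization of the ratios reduced the counts to 1677 higher and 1508 lower genes. It also ended the calls of 20 genes named in the text, which were Sst, Slc38a5, Ttr, Hhex, Amy2b, Rnase1, Spp1, Car2, Mpeg1, Flt1, Hba-a1, Ahsp, Hk2, Zyx, Rrm2, Uqcrh, Uchl3, Nr1d1, Per3 and Rdh10.

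The reference was db/+ islet RNA of the same age, so ratios of db/+ arrays hold no genotype difference by construction, and the spread of ratios and the authors' p-values are to be read with this in mind. Whether the reference was pooled from the same db/+ mice is not given, and if so the spread of the db/+ ratios would be reduced. The standard deviation of the log2 ratios was 0.506 ± 0.0257 (SD, n = 5) on db/db arrays and 0.231 ± 0.0472 (SD, n = 5) on db/+ arrays. The authors' deposited p-values, which compare the channels of each array, were under 0.01 for 3274 to 4442 probes on db/db arrays and for 144 to 585 on db/+ arrays. In the Cy3 channel, which held the control reference on every array, 5 of 23138 probes passed the same limma threshold between the arrays of the groups, and 1113 had an unadjusted p under 0.05 (4.81%). For Cck, Cyp26b1 and Klk8 the Cy3 signal was not alike in both groups, as described below, so this count does not clear every gene.

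**Figure D1:**
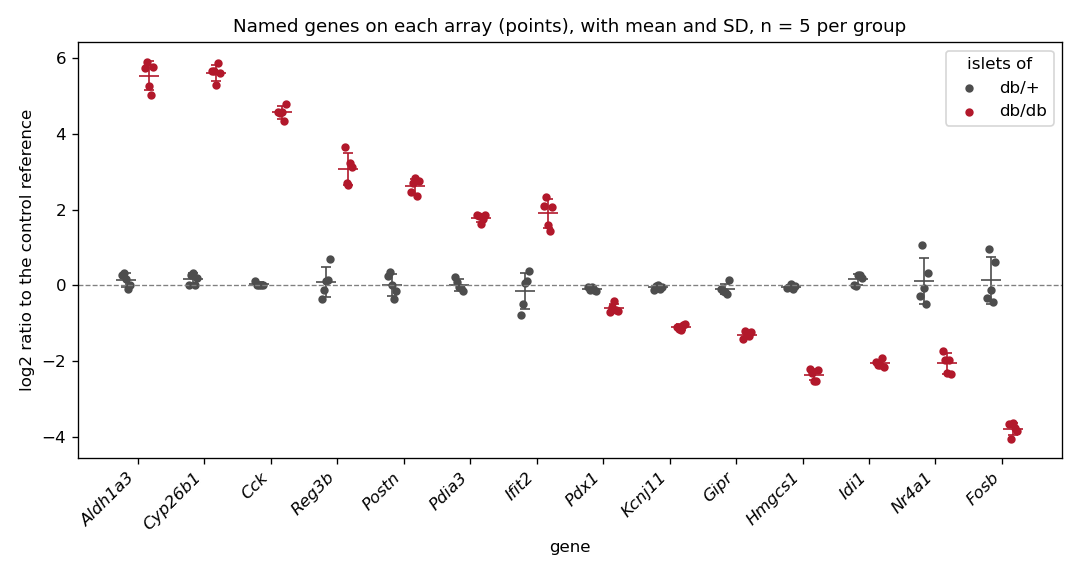
Log2 ratio to the control reference (vertical axis) of named genes (horizontal axis) on each array, with points for single arrays and the mean with SD for each group of 5. For each gene the 5 db/db points lie apart from the 5 db/+ points, from Cyp26b1 at 5.45 above db/+ to Fosb at -3.93. Most of these genes were chosen for large differences or small adjusted p-values in these data.

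Lepr, the gene that carries the db allele, was listed at a mean reference intensity of 0.0117 units, under the limit for dim probes, and did not pass the test (log2 difference -0.41 ± 0.37 SE, adjusted p = 0.445). The position of its probe in the gene was not given, so this value does not check the genotypes. Pdx1, a beta cell transcription factor, fell 1.42-fold (log2 difference -0.51 ± 0.06 SE, adjusted p = 0.000115). For the insulin gene transcription factor Mafa the probe was dim (0.045 units), all db/+ ratios were 0, and the db/db values lay 1 rounding step of 0.01 units under the reference, so no change is read from it. It missed the threshold in the Cy5 signal without the reference (adjusted p = 0.0619, with a range of 1.81e-05 to 0.0619 over all alternatives). Sst, the somatostatin gene, was lower in db/db (adjusted p = 0.0033, with 3 db/+ values), at a mean reference intensity of 16.1 units, where many values were blank and the sizes of ratios are uncertain. The probe listed for Ins1, an insulin gene, lay at 0.044 units with nearly all ratios at 0, and the positions of the Ins1 and Mafa probes were not given, so whether Ins1 changed is not shown. Txnip, a glucose-induced gene, gave -0.08 ± 0.15 SE (adjusted p = 0.713). No probe was listed for Ins2, which was not analysed here.

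Some of the most abundant islet transcripts had fewer than 3 values in a group and could not be tested between the groups. Slc2a2, the glucose transporter of mouse beta cells, had 5 db/db values and 0 db/+ values, and its mean log2 ratio to the control reference in db/db was -2.08 ± 0.33 (SD, n = 5). Slc30a8, the zinc transporter of insulin granules, lay at -0.90 ± 0.23 (SD, n = 5) against the same reference, and Iapp, the islet amyloid gene, at 0.29 ± 0.19 (SD, n = 3). Gcg, the glucagon gene, had 0 db/db values and 2 db/+ values, and Ppy, pancreatic polypeptide, had 1 and 3. The reference lay at a mean of 18.6 units for Slc2a2 and 18.5 for Slc30a8, near the highest Cy3 values of the db/db arrays (17.88 to 20.43), so the sizes of these ratios are uncertain. These ratios leave out the spread of the control.

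Among the largest rises in db/db, Cyp26b1 rose 43.8-fold (log2 difference 5.45 ± 0.11 SE, adjusted p = 1.36e-08) and Aldh1a3 42.3-fold (5.40 ± 0.18 SE, adjusted p = 2.06e-07). Cck, which encodes the peptide hormone cholecystokinin, rose 23.3-fold and the serine protease gene Klk8 22.8-fold. Mean Cy5 intensities in db/db and db/+ were 11.8 and 0.128 units for Cck, 13.4 and 0.146 for Cyp26b1, and 6.21 and 0.112 for Klk8. These gaps are wider than the folds, so the Cy3 signal was not alike in both groups for these genes. Their folds and ranks are therefore uncertain, while the gap of Aldh1a3 (7.59 and 0.162 units) was near its fold. Bcat1, an aminotransferase of branched-chain amino acids, rose 21.4-fold, and Morc1 17.8-fold, both from reference intensities under 0.05 units, where values are rounded to 0.01 and the folds are coarse. The remaining rises among the largest 10 were in Arpc3, a subunit of the actin-nucleating Arp2/3 complex, Reg2, the haem oxygenase gene Hmox1 (12.6-fold) and Reg3g (11.1-fold). The log2 difference of Hmox1 was 3.65 ± 0.57 SE. Its db/+ log2 ratios ran from -1.57 to 1.72, the highest on replicate 1, so the size of its rise is uncertain. Mean Cy5 intensities in db/db were 15.6 units for Arpc3 and 15.5 for Reg2, near the top of the scale, so their folds and ranks are uncertain. Fosb fell 15.2-fold (-3.93 ± 0.27 SE, adjusted p = 7.37e-06), Cox6a2 11.7-fold and the immediate early gene Egr4 11.1-fold. Further falls were in Cplx3, a complexin of vesicle fusion (7.56-fold), T2 (5.80-fold), Mlf1 (5.68-fold), Pdzrn4 (5.65-fold), the phosphatidate phosphatase gene Lpin1 (5.50-fold), the zinc exporter gene Slc30a1 (5.46-fold) and the stress-induced transcription factor gene Atf3 (5.42-fold). Mean Cy5 intensities in db/db were 0.032 units for Cplx3 and 0.048 for Egr4, so their folds and ranks are coarse. All of these genes were separated between the groups on all 10 arrays.

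Of 35 gene lists fixed before the data were examined, 9 were called higher and 5 lower by camera with a preset correlation, 0 with an estimated correlation (3 at an unadjusted p under 0.05, which were beta cell, cholesterol synthesis and hypoxia), and 20 by fry, which added the alpha cell, duct cell, endothelial, adipocyte, antioxidant and serotonin response lists. In 9 of 100 splits of the 10 arrays camera called as many lists, so chance is not excluded for the number of called lists. The 8 of these splits other than the real one all kept 4 arrays of a genotype together and so held most of its contrast, and the 79 that kept 3 together called 0 to 12 lists.

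Beta cell markers were lower in db/db islets: 11 of 23 fell, Mafa counted among them, and 2 rose, with a median log2 difference of -0.21 (camera adjusted p = 0.00244, adjusted p = 0.306 with an estimated correlation). The counts adjusted over the list alone were the same. Without the dimmer probes, below the median intensity, the list missed the threshold although its median was -0.31 (adjusted p = 0.059, with a range of 3.67e-05 to 0.059 over all alternatives). Kcnj11, the pore of the ATP-sensitive potassium channel, fell 2.07-fold (-1.05 ± 0.04 SE), the incretin receptor gene Gipr 2.30-fold (-1.20 ± 0.07 SE) and the cation channel gene Trpm5 1.52-fold. Genes of immature endocrine cells and dedifferentiation rose more often than they fell, with 7 higher and 1 lower of 16 (7 and 2 adjusted over the list alone, camera adjusted p = 0.00996, adjusted p = 0.433 with an estimated correlation). Aldh1a3, Cck and Serpina7, a thyroxine-binding globulin that rose 5.68-fold, led this list. Among 23 genes that normal beta cells repress, 10 rose and 2 fell, the same adjusted over the list alone (camera adjusted p = 0.0284, adjusted p = 0.55 with an estimated correlation), including ornithine aminotransferase Oat (2.04-fold higher), hexokinase Hk2 (2.29-fold higher), catalase Cat (1.52-fold higher) and Zyx (1.43-fold lower). The call of this list was lost without db/db replicate 1 (adjusted p = 0.0535), after quantile normalization (0.136), without the dimmer probes (0.0691), with all tested genes in the list test (0.0817) and without both arrays of largest spread (0.0728, median 0.12 against 0.28), within a range of 0.00405 to 0.136 over all alternatives.

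Markers of other endocrine cells went both ways. Of 8 alpha cell genes 3 rose and 1 fell (4 and 1 adjusted over the list alone, median 0.24, camera adjusted p = 0.189), with the amino acid transporter gene Slc38a5 1.59-fold and transthyretin Ttr 1.70-fold higher. Of 7 delta and PP cell genes 1 rose and 2 fell, the same adjusted over the list alone (median -0.12, camera adjusted p = 0.972): Hhex, a delta cell transcription factor, rose 1.43-fold, and the retinol carrier gene Rbp4 fell 2.17-fold together with Sst. Secretory granule and exocytosis genes were split, with 13 of 35 higher and 11 lower (14 and 11 adjusted over the list alone, camera adjusted p = 0.915). Within that list the granule membrane protein gene Ptprn rose 2.51-fold and the granuphilin gene Sytl4 fell 4.01-fold, while the granule peptide gene Vgf rose to a mean Cy5 intensity of 19.9 units in db/db, too bright for an exact fold. The median of the list was -0.12, whereas its mean was 0.05 and its test pointed up.

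Among tested genes of protein folding and degradation in the endoplasmic reticulum, more rose than fell in db/db islets. Only 26 of the 34 listed genes on the array were tested, as others had too few values. Mean log2 ratios in db/db and db/+ were 0.10 and 0.19 for the chaperone gene Hspa5 (1 and 2 values). They were -0.27 and 0.13 for Canx (1 value each), 0.36 and -0.09 for Calr (2 each) and 0.86 and -0.16 for Dnajc3 (5 and 2). Of 26 chaperone and ERAD genes 13 rose and 2 fell (14 and 2 adjusted over the list alone, median 0.24, camera adjusted p = 0.000302, adjusted p = 0.44 with an estimated correlation). The disulfide isomerase gene Pdia3 rose 3.42-fold (1.78 ± 0.08 SE) on its brighter probe, and its other tested probe was not called. The degradation factors Derl3 and Sel1l rose 3.00-fold and 2.00-fold. The integrated stress response did not move one way, with 6 of 28 genes higher and 5 lower (7 and 5 adjusted over the list alone, median -0.01, camera adjusted p = 0.839). In this list the secreted factors Stc2 and Gdf15 rose 1.59-fold and 2.09-fold and Atf3 fell. Its median and mean were negative and its test pointed up, and the median turned to 0.01 after quantile normalization and to 0.03 after loess within arrays. Cytosolic ribosomal protein genes rose, with 17 of 35 higher and 1 lower (18 and 1 adjusted over the list alone, median 0.32, camera adjusted p = 0.000363, adjusted p = 0.487 with an estimated correlation), among them Rplp0 (1.87-fold) and Rps3, whose call was lost in the Cy5 signal without the reference (adjusted p = 0.133, with a range of 3.55e-05 to 0.133 over all alternatives). Of 30 proteasome and ubiquitin genes 6 rose and 6 fell, the same adjusted over the list alone (median -0.06, camera adjusted p = 0.839), with the proteasome ATPase gene Psmc6 1.65-fold lower and the ubiquitin hydrolase gene Uchl3 1.34-fold higher. Hypoxia genes rose, 12 of 21 against 3 that fell, the same adjusted over the list alone (median 0.30, camera adjusted p = 0.0122, adjusted p = 0.282 with an estimated correlation), including Ankrd37 (2.54-fold), the prolyl hydroxylase gene P4ha2 (1.95-fold) and the pyruvate dehydrogenase kinase gene Pdk1 (1.74-fold). This call was lost after quantile normalization (adjusted p = 0.167) and without the dimmer probes (0.0691, with a range of 0.00477 to 0.167 over all alternatives). Of 29 antioxidant genes 11 rose and 5 fell (12 and 5 adjusted over the list alone, median 0.17, camera adjusted p = 0.0545). The peroxiredoxin of the endoplasmic reticulum Prdx4 rose 2.13-fold and metallothionein Mt1 fell 5.30-fold, while the extracellular superoxide dismutase Sod3 rose from a reference intensity of 0.039 units, too low for an exact fold. The antioxidant list passed without db/+ replicate 1 (adjusted p = 0.0266), 3 (0.0367), 4 (0.0171) or 5 (0.0254) and without db/db replicate 5 (0.0284), without both arrays of largest spread (0.0256), in the mean of a gene's probes (0.0348) and with the acinar marker mean as a covariate (0.0257), within a range of 0.0171 to 0.186 over all alternatives.

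The pathway of cholesterol synthesis fell as a group in db/db islets, with 16 of 21 genes lower and 1 higher, the same adjusted over the list alone (median -0.70, camera adjusted p = 1.26e-07, adjusted p = 0.207 with an estimated correlation). Hmgcs1, the HMG-CoA synthase gene, fell 4.97-fold (-2.31 ± 0.07 SE, adjusted p = 1.52e-07), Idi1 4.64-fold, Mvd 2.44-fold and Lss 1.81-fold, all enzymes of the mevalonate and sterol pathway. Fatty acid synthesis genes also fell, 9 of 23 against 1 that rose, the same adjusted over the list alone (median -0.20, camera adjusted p = 0.00831, adjusted p = 0.44 with an estimated correlation). Besides Lpin1, the acyl-CoA synthetase gene Acsl3 fell 3.34-fold, the desaturase gene Fads2 2.13-fold and the elongase gene Elovl6 1.95-fold. Fatty acid oxidation and PPAR target genes went both ways, 8 of 35 higher and 7 lower, the same adjusted over the list alone (median 0.04, camera adjusted p = 0.577). In that list the lipid droplet coat gene Plin2 rose 2.35-fold and lipoprotein lipase Lpl fell 4.04-fold. The fatty acid binding protein gene Fabp5 rose too, from 0.056 units with all db/+ ratios at 0, too low for an exact fold.

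In glucose and mitochondrial metabolism, genes of the TCA cycle and anaplerosis fell. Of 30 tested 12 fell and 2 rose (16 and 3 adjusted over the list alone, median -0.26, camera adjusted p = 0.0252, adjusted p = 0.55 with an estimated correlation), and the call was lost without db/db replicate 1 (adjusted p = 0.0555), without the dimmer probes (0.122), with all tested genes in the list test (0.107) and without both arrays of largest spread (0.0635, with a range of 0.00861 to 0.122 over all alternatives). Pyruvate carboxylase Pcx fell 2.18-fold and the mitochondrial glycerol phosphate dehydrogenase gene Gpd2 2.26-fold, while the malic enzyme gene Me3 rose 2.44-fold. Oxidative phosphorylation genes were divided, with 17 of 64 higher and 10 lower, the same adjusted over the list alone (median 0.04, camera adjusted p = 0.597). Among them, Uqcrh of complex III rose 1.39-fold. The median turned to -0.01 in the Cy5 signal without the reference. Of 22 glycolysis genes 6 rose and 8 fell (7 and 8 adjusted over the list alone, median 0.04, and -0.07 in the Cy5 signal without the reference, camera adjusted p = 0.9). The gluconeogenic fructose bisphosphatase gene Fbp2 rose 8.13-fold, from a reference intensity of 0.07 units, and Pfkfb2, which controls fructose 2,6-bisphosphate, fell 2.32-fold. Of 11 glucose responsive genes 4 rose and 3 fell (4 and 5 adjusted over the list alone, camera adjusted p = 0.987). Arrdc4, a relative of Txnip, rose 2.54-fold and the transcription factor gene Hnf4a fell 2.07-fold. The median of this list was -0.18, while its mean was 0.02 and its test pointed up.

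**Figure D2:**
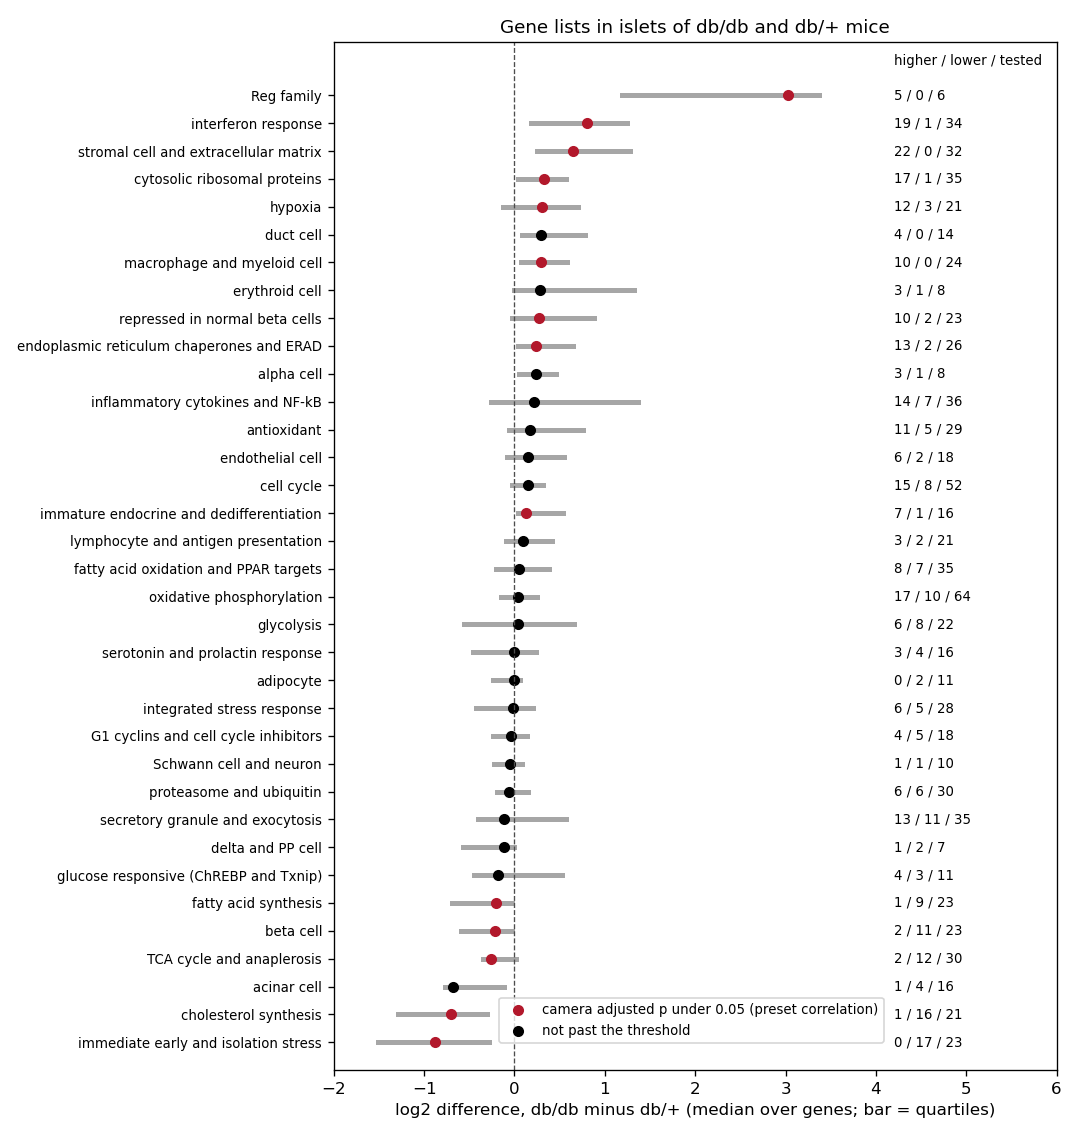
Median log2 difference between db/db and db/+ islets (horizontal axis) over the tested genes of each of the 35 lists (vertical axis), with a bar from the lower to the upper quartile of the genes. Red points are lists called by camera with the preset correlation, and the numbers give genes higher, lower and tested. The Reg family lies at 3.03 and the interferon response at 0.80, and the immediate early genes lie at -0.88.

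Markers of stromal cells and of macrophages were higher in db/db islets. Of 32 stromal and extracellular matrix genes 22 rose and 0 fell, the same adjusted over the list alone (median 0.65, camera adjusted p = 1.26e-07, adjusted p = 0.433 with an estimated correlation). The collagen gene Col3a1 rose 6.55-fold (2.71 ± 0.27 SE), the matrix protein gene Postn 6.07-fold (2.60 ± 0.15 SE) and the pericyte receptor gene Pdgfrb 2.63-fold. Of 24 macrophage and myeloid genes 10 rose and 0 fell, the same adjusted over the list alone (median 0.29, camera adjusted p = 0.00357, adjusted p = 0.55 with an estimated correlation), and this call was lost after quantile normalization (adjusted p = 0.0884, with a range of 0.00122 to 0.0884 over all alternatives). Gpnmb and Lgals3, which lipid-laden macrophages express, rose 7.74-fold (from 0.069 units, a coarse fold) and 4.17-fold, and the macrophage gene Mpeg1 1.75-fold. Endothelial markers went both ways, with 6 of 18 higher and 2 lower (7 and 2 adjusted over the list alone, median 0.15, camera adjusted p = 0.189). Sox18, an endothelial transcription factor, rose 2.60-fold and the VEGF receptor gene Flt1 fell 1.75-fold. Of 21 lymphocyte and antigen presentation genes 3 rose and 2 fell (3 and 1 adjusted over the list alone, median 0.09, camera adjusted p = 0.326), with H2-DMa 1.94-fold and the B cell receptor gene Cd79a 1.38-fold higher.

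Exocrine markers did not rise together. Of 16 acinar genes 1 rose and 4 fell (1 and 9 adjusted over the list alone, median -0.68, camera adjusted p = 0.0545), with the ribonuclease gene Rnase1 2.56-fold lower and the trypsinogen gene Prss3 3.94-fold higher. Pancreatic amylase Amy2b was lower too, at a reference intensity of 15.9 units, where the size of the ratio is uncertain as for Sst. Of 14 duct genes 4 rose and 0 fell, the same adjusted over the list alone (median 0.30, camera adjusted p = 0.0545), among them osteopontin Spp1 and carbonic anhydrase Car2. The call of Spp1 was lost in the Cy5 signal without the reference (adjusted p = 0.32, with a range of 9.29e-05 to 0.32 over all alternatives). The log2 difference of Car2 was 2.54 ± 0.68 SE, and 3.17 without db/+ replicate 1, whose ratio of 1.85 lay far above the other db/+ arrays, so its size is uncertain. The acinar list passed without db/+ replicate 3 (adjusted p = 0.03) or 4 (0.0418) and without db/db replicate 2 (0.00196), without both arrays of largest spread (0.0016), in the Cy5 signal without the reference (0.0139), without the dimmest 25% of probes (0.0433) and after loess (0.0306), within a range of 0.0016 to 0.487 over all alternatives. The duct list passed without db/+ replicate 1 (adjusted p = 0.0136) and without db/db replicate 3 (0.0312), with the replicate block (0.0295), in the Cy5 signal without the reference (0.0431), without the dimmest 25% of probes (0.0433) and with the acinar marker mean as a covariate (0.0165), within a range of 0.0136 to 0.255. Rnase1 and Car2 missed the threshold in an exact permutation test per gene (adjusted p = 0.052 and 0.0883), in which Sst was not tested. Genes of the Reg family, secreted lectins of the pancreas, rose in db/db, 5 of 6 with 0 lower, the same adjusted over the list alone (median 3.03, camera adjusted p = 0.000921, adjusted p = 0.44 with an estimated correlation). Reg3a rose 8.45-fold, beside Reg2, Reg3g and Reg3b, whose size is uncertain at a mean Cy5 intensity of 16.5 units in db/db. Members of this family have similar sequences and no probe sequence was used here, so signal shared between them cannot be excluded, which holds for amylases, trypsinogens and globins too. Of 8 erythroid genes 3 rose and 1 fell, the same adjusted over the list alone (median 0.28, camera adjusted p = 0.548), with the globin gene Hba-a1 2.66-fold higher and the haemoglobin chaperone gene Ahsp 1.51-fold lower. Adipocyte markers had 0 of 11 higher and 2 lower, the same adjusted over the list alone (median -0.01, turning to 0.01 after loess, mean above 0, test down, camera adjusted p = 0.548), and 6 of them were dim. Schwann cell and neuron markers had 1 of 10 higher and 1 lower, the same adjusted over the list alone (median -0.05, camera adjusted p = 0.86).

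Interferon response genes rose in db/db islets, 19 of 34 against 1 that fell, the same adjusted over the list alone (median 0.80, camera adjusted p = 2.75e-06, adjusted p = 0.469 with an estimated correlation). Ifit2 rose 4.13-fold, the oligoadenylate synthetase gene Oas2 3.40-fold and the RNA sensor gene Ifih1 2.99-fold. Inflammatory cytokine and NF-kB genes were mixed, with 14 of 36 higher and 7 lower (17 and 8 adjusted over the list alone, median 0.21, camera adjusted p = 0.105). The decoy receptor genes Tnfrsf11b and Il1r2 rose 4.19-fold and 2.31-fold, and the NF-kB subunit gene Relb fell 3.20-fold. The list passed without db/+ replicate 1 (adjusted p = 0.0397), in the Cy5 signal without the reference (0.0405) and with the acinar marker mean as a covariate (0.0257, with a range of 0.0257 to 0.357 over all alternatives). Immediate early and isolation stress genes fell, 17 of 23 with 0 higher, the same adjusted over the list alone (median -0.88, camera adjusted p = 0.000278, adjusted p = 0.469 with an estimated correlation). Besides Fosb, the nuclear receptor gene Nr4a1 fell 4.51-fold (-2.17 ± 0.28 SE) and Jun 3.10-fold (-1.63 ± 0.22 SE). A difference in islet isolation or handling between the groups was not tested and cannot be told apart from genotype here. The same limit holds for the immediate early gene Egr4.

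Cell cycle genes did not pass as a group, with 15 of 52 higher and 8 lower, the same adjusted over the list alone (median 0.15, camera adjusted p = 0.0545). Rrm2, a ribonucleotide reductase subunit, rose 1.49-fold and the replication helicase gene Mcm4 fell 2.51-fold. The list passed without db/+ replicate 1 (adjusted p = 0.0135) or 4 (0.0459) and without db/db replicate 2 (0.0397) or 4 (0.0408), with the replicate block (0.0341) and without both arrays of largest spread (0.0314), within a range of 0.0135 to 0.713 over all alternatives. Of 18 G1 cyclins and cell cycle inhibitors 4 rose and 5 fell, the same adjusted over the list alone (camera adjusted p = 0.972), with Ccnd2 1.66-fold lower and the p53 target Ccng1 1.73-fold higher. The median and mean of that list were -0.04 and its test pointed up, and the median turned positive after quantile normalization (0.05), after loess (0.0037) and in the Cy5 signal without the reference (0.01). Of 16 genes of the serotonin and prolactin response 3 rose and 4 fell, the same adjusted over the list alone (median -0.0035, turning to 0.03 after quantile normalization and 0.04 after loess, mean -0.13, camera adjusted p = 0.86), with the cytokine signalling inhibitors Cish and Socs2 3.11-fold and 2.06-fold lower.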

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

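The tests of the Lepr neighbourhood, of the total gene count and of the clock genes were written down before their results were seen, though falls of Dbp, Per2, Hlf and Nfil3 had been seen, and the tests of stromal, myeloid and Reg genes, of the list count and of the reference channel were chosen after.

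Chance splits of the arrays were tried for each count. Of 100 drawn from the 126 splits of the 10 arrays into 5 and 5, only the real one (1 of 100) called as many as 6893 genes. The highest other called 4, which argues against chance for the gene count. All other splits mix the genotypes, which widens the spread within their parts and lowers their counts, so the gap itself is no measure of chance. The 14 gene lists called by camera were matched by 9 of 100 splits, the real one included, with up to 16 lists in another split, so chance is not excluded for the number of lists. The 8 other splits each kept 4 arrays of a genotype together, so they held most of the genotype contrast, and the 79 splits that kept 3 together called at most 12 lists. The 5 reference probes past the threshold were matched by 10 of 100 splits, with up to 10 probes. Whether Cck, Cyp26b1 or Klk8, whose Cy3 signal was not alike in both groups, are among these probes is not given here.

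Markers of stroma rose with the db/db group, and those of myeloid cells to a smaller extent. A lower share of endocrine cells would raise the markers of all other cell types alike. The stromal score minus the endothelial score was 0.49 higher in db/db on the log2 scale (exact permutation p = 0.00794, the smallest possible). This argues against that share as the whole cause for stroma. The endothelial score itself was 0.16 higher in db/db (exact permutation p = 0.0159), so a lower endocrine share as part of the cause stays open. For myeloid markers the difference to the endothelial score was 0.19 (exact permutation p = 0.0952), so a real myeloid rise and a lower endocrine share cannot be told apart. The acinar score was lower in db/db (difference -0.55, exact permutation p = 0.0397), so more acinar tissue in db/db was not seen. With that score of each array in the fit the stromal median was 0.87 (camera adjusted p = 2.93e-08), and with the mean of the acinar markers 0.80 (1.69e-08). Since the score fell in db/db, this fit could hardly remove a stromal rise, and it decides nothing about acinar carry-over. Carry-over of duct tissue was not tested and stays open, as 4 of 14 duct genes rose and 0 fell (median 0.30). A change of stroma with the genotype stays open as a hypothesis.

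Reg genes rose in db/db while the acinar score fell. The lowest Reg score of a db/db array exceeded the highest of a db/+ array by 1.79, whereas no db/db array exceeded a db/+ array by more than 0.43 in the acinar score, a margin of 1.36. The difference of the acinar score, db/db minus db/+, was -0.55 (exact permutation p = 0.0397). Only 16 of 28 acinar genes on the array were tested, as bright ones such as Cpa1 and Cela2a had too few values. Ratio sizes near the top of the scale are uncertain, so this score cannot bound the acinar content. A rise of Reg genes inside carried-over acinar cells was not tested. A single array as the source is argued against, as the Reg median was at least 2.87 whichever db/db array was left out. Signal shared between Reg probes was not tested, and a rise of Reg genes within islets stays open as a hypothesis.

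Of 14 clock genes tested, 12 were lower in db/db, as described among the other observations, and no test of them as a group was run. If islets of the groups had been collected at opposite phases of the day, Arntl and Npas2, which peak opposite to Dbp and Per2, would be higher in db/db. The higher of both log2 differences was -0.0275 (Npas2, a probe of low intensity) and Arntl fell (-1.42 ± 0.11 SE), and the fall of Arntl argues against opposite phases. A smaller shift of phase, or a difference in handling on the day, was not tested and may remain, since collection times are not given in the sources used here.

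Some values stood apart from the other arrays of their group by the ratio of the gap to the range (over 0.71 for 5 values), in 10 of 263 groups compared (3.8%), where chance sets about 1 in 20 apart. On db/db replicate 2 these were Txnip at a log2 ratio of 0.43, Klk8 at 5.46 and Acsl3 at -2.14. On db/db replicate 1 they were Ptprn at 1.53 and Oas2 at 0.93, and on db/db replicate 4 Pdk1 at 0.88 and Npas2 at -0.14. In db/+, Cck stood apart at 0.13 on replicate 1 while its other ratios were 0, and Sytl4 at 0.28 on replicate 4. Blank values numbered 855 on db/+ replicate 1 and 318 to 421 on the other db/+ arrays. Among 1239 tested probes without a gene name, 127 were higher and 145 lower in db/db by limma.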

How the results depend on the processing

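Loess within arrays, the list test on all genes and leaving out both arrays of largest spread were chosen after the data were seen. Under most settings the counts stayed within 1.5 times the reported ones (2296 to 3756 genes higher in db/db and 2455 to 3946 lower). They were 1677 and 1508 after quantile normalization, which gives all arrays the same spread by construction, and 1466 and 1132 where a fold of 1.5 was required, and 2260 genes were lower at an adjusted p under 0.01. Called lists numbered 9 without probes under the median intensity, where 13 of the 14 could be tested and 4 lost their call (beta cell, repressed in beta cells, TCA cycle and hypoxia), and 0 with an estimated correlation by camera (3 at an unadjusted p under 0.05), against 20 by fry. Leaving out each array gave 2960 to 3299 higher and 3075 to 3492 lower genes, 12 to 18 lists and 2 to 7 reference probes. The reference channel probes past the threshold were 3 after scaling to the 75th percentile. With the replicate block they were 0 by limma (903 at an unadjusted p under 0.05), beside 3250 higher and 3528 lower genes and 16 lists (duct cell and cell cycle added). After each group's mean was taken from every gene, same-numbered arrays correlated by 0.0492 to 0.204 across genes. Most were closer to another number, so the numbers were not taken to pair the mice. Of 121 called genes followed under the alternatives, none lost its call in 1207 comparisons without 1 array, and 27 of 1431 calls ended under other settings, of which 20 after quantile normalization. Most of the followed genes were chosen for large differences or small adjusted p-values in these data. Their stability therefore does not carry over to all called genes. Sst, with 8 values, was not tested by exact permutation. The log2 difference of Car2 was 2.54, and 3.17 without db/+ replicate 1. Medians near 0 changed sign, and the cause was not tested. After quantile normalization they were 0.0079 for the integrated stress response, 0.048 for G1 cyclins and 0.030 for the serotonin response. In the Cy5 signal without the reference they were 0.014 for G1 cyclins, -0.0062 for oxidative phosphorylation and -0.073 for glycolysis. Without the dimmest 25% of probes they were -0.0064 for endothelial, 0.041 for Schwann cell and 0.0154 for G1 genes, and without probes under the median intensity 0.0154 for G1 genes, -0.12 for glycolysis and -0.012 for fatty acid oxidation. The mean of a gene's probes gave -0.014 for fatty acid oxidation. With the acinar covariate, values were 0.16 for Txnip, -0.0096 for lymphocyte, 0.026 for adipocyte and 0.064 for G1 genes. Loess gave 0.011 for adipocyte, 0.030 for integrated stress, 0.0037 for G1 and 0.043 for serotonin genes. Without both arrays of largest spread, values were 0.0081 for integrated stress, -0.00028 for oxidative phosphorylation, -0.011 for glycolysis and 0.014 for serotonin genes. Leaving out each array gave -0.14 to 0.076 for integrated stress, -0.075 to 0.037 for G1 and -0.051 to 0.024 for serotonin genes. Signal over background was not given, so what it limits is unknown beyond the coarse ratios of dim probes.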

Other observations

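The Lepr test was set before its result was seen, and the other genes of this part were chosen after their values were seen, except where they are named in the report. Of 14 tested genes of the circadian clock 12 were lower in db/db, 1 was higher and 1 was not called. No test of the clock genes as a group was run. The output genes Dbp (3.69-fold) and Hlf (3.91-fold) fell, and so did Per2 (3.61-fold), Nfil3 (3.93-fold), Cry1 (2.98-fold), Nr1d1 (2.22-fold) and Clock (1.58-fold). Arntl fell as well (2.67-fold, log2 difference -1.42 ± 0.11 SE, adjusted p = 1.67e-05). Dbp and Arntl peak at opposite times of day in most tissues. Per3 rose 1.20-fold, but missed the threshold in the mean of its probes (adjusted p = 0.758) and in the Cy5 signal without the reference (0.0981). The calls of Nr1d1, Per3 and Rdh10 ended after quantile normalization.

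Of 20 tested genes of retinoid metabolism and signalling 9 were higher in db/db, Aldh1a3 and Cyp26b1 among them, 2 were lower and 9 were not called. No test of the family was run. The receptor gene Rarb, itself a target of retinoic acid, rose 2.42-fold (1.27 ± 0.15 SE), and the retinaldehyde enzymes Dhrs3 and Rdh10 1.72-fold and 1.69-fold, while Rdh11 fell 2.11-fold and Rbp4 2.17-fold. Zinc transporters, metallothioneins and the transcription factor gene Mtf1 went both ways, with 6 of 24 tested higher and 5 lower, Mtf1 among the lower. Mt1 and Slc30a1, which zinc induces, fell 5.30-fold and 5.46-fold, and Mt2, with 1 db/+ value and a reference intensity of 16.4 units, could not be tested. The zinc transporter gene Slc39a13 rose 1.75-fold, and Slc39a11 rose on a probe too bright in db/db for an exact fold.

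A hypothesis was that variants linked to the db allele give differences near Lepr. Of 110 tested genes within 10 Mb of Lepr in assembly GRCm38.p6, 44 were called, against 6645 of 18584 genes elsewhere (odds ratio 1.20, 95% interval 0.798 to 1.78, Fisher's exact p = 0.37), so an excess was not detected.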
